A study of Mus musculus with 37 samples.

How the data were processed

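RNA of peripheral blood cells of female NOD mice was hybridised with RNA of NOD.B10 mice on Agilent whole mouse genome arrays, 37 in all, with Cy3 on NOD and Cy5 on NOD.B10 on every array and no swap of the dyes, per the labels; the series text gives the sex. RNA was extracted with the Qiagen RNeasy kit and amplified linearly with Agilent's low-input labelling kit, per the labels' protocols. The labels give every NOD sample the disease state diabetic, 10 days included, so disease state was not used. The deposited scanner files give each spot's intensity in both colours, with the median of its local background, per the file headers. They also give processed intensities, which the scanner software had background-subtracted and dye-normalized (linear and LOWESS) within the array, and a log10 ratio of Cy5 over Cy3 per the file headers. The authors' value table holds a log10 ratio of NOD over NOD.B10. It equalled minus the scanner's log10 ratio to within 5e-05 on every array, which settled its scale and direction. Its median was 0 on every array but 10 days replicate 1, where it was 0.0018, and neither scale, centring nor direction stays unknown. The file headers name Feature Extraction 8.1.1.1 and 9.1.3.1, and the submitters' processing notes name 8.5.

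Each array held 43790 spots, of which 41534 were not controls and 41174 were different probes. Background was corrected by normexp (offset 50) on the mean signals and the log2 ratios of Cy3 over Cy5 were normalized by loess (span 0.3) within each array, without scaling between arrays, in limma 3.58.1 under R 4.3.3 with the package data.table (version 1.17.8). Control spots had weight 0 in loess and were then left out, as were spots marked as outliers by the scanner software. Spots of 1 probe were averaged. A probe was kept when it was well above background in either colour on at least 80% of the arrays of an age, and 30136 probes passed. This filter was chosen after the files, and single probes in them, had been looked at. Names came from the RefSeq table (GRCm38.p6): 21445 probes matched by accession, 10067 by symbol or synonym, and 9662 kept the name in the file. The brightest probe stood for a gene, which left 22184 genes, 15831 of them with a symbol. Of 6038 genes with several probes, probes were called in both directions in 839 for the strain ratio over ages, 294 for later ages minus 10 days, 392 for the trend, 336 for 12 weeks minus 10 days, 16 for 16 weeks minus 10 days and 231 for 16 weeks minus 12 weeks.

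All 37 arrays entered 1 limma fit with a mean per age, and contrasts gave the strain ratio over ages and at each age, each age against 10 days, successive ages, the slope from 4 to 20 weeks and a moderated F test over the 5 later ages. Tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The reference channel was tested by a moderated F test on Cy5 after loess and Aquantile normalization. The ratio against 0 is the strain comparison, and it leaves out the spread of the reference mice. The NOD.B10 groups named in the series text are of 10 days and 20 weeks. At other ages the ratio may therefore also hold a difference of age. The groups, the tests, 28 gene lists, the rule for named genes and most alternatives were set before the data were examined. The lists, of blood cell types, immune and metabolic groups, MHC genes, candidate susceptibility genes and transcripts not expected in blood, were tested with camera (preset correlation 0.01), with adjustment over all lists in the strain ratio over ages, the later ages minus 10 days and the trend together, and again with an estimated correlation, with which no list passed in any of 6 contrasts. The same test on the 3 contrasts within the shared scan day, adjusted as a family of its own, and exact permutation tests of the lists' medians per array (84 tests, and again without an array far from the others of its age), were added after results had been seen.

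Named genes passed adjusted p 0.05, had a symbol and were well above background in both colours on a share of at least 0.5 of the arrays of each age compared. For the strain ratio over ages a gene also had 1 sign on at least 35 of 37 arrays, and for later ages minus 10 days each of the 5 single contrasts passed in the same direction. The 12 largest rises and falls were taken for these and for the trend, 3 each for single contrasts and 6 by range for the F tests. Genes saturated in a colour on every array of an age compared, and names of the MGC clone type, were left out of this naming after their values had been seen. Some genes that met the rule are not reported here. Genes that missed only the background rule were given as at-least folds, with up to 5 per direction, and up to 4 members were named per list. The highest Cy3 correlation was 0.981 (12 weeks replicates 1 and 3), with 2 identical values. No array was a copy, so all were kept, but this cannot reveal shared RNA.

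The fit and the list test were run on simulated data with 200 of 22184 genes changed by 0.5, 1 or 2 log2 units. Log ratios were drawn as independent normal values with each gene's spread. Normalization, the probe filter, correlation between genes and scan days were not simulated, so the shares below do not cover them. For 12 weeks minus 10 days 80.6%, 94.0% and 100% of the changed genes were recovered, with 5 false calls. For 16 weeks minus 10 days the shares were 71.6%, 95.5% and 97.0% with 8 false calls, and for 16 weeks minus 12 weeks 74.6%, 94.0% and 100% with 7. For later ages minus 10 days they were 83.6%, 94.0% and 100% with 6, for the trend 73.1%, 92.5% and 97.0% with 10, and for the strain ratio over ages 100% at each size with 11. Each array is measured by its spot signals, so the number of arrays, not a depth, limits the precision. Alternatives changed 1 choice at a time: signals, the authors' value table, normalization, background, filter, probes, array weights, a 2-fold minimum, a block for replicate number, single arrays of 4 and 20 weeks left out, the NOD channel alone and subsets of ages. For the trend the 2-fold minimum was read as the slope over 16 weeks and for F tests as the range of age means, readings set after first counts. The offset of 10, the runs without saturated probes or without probes bright at 4 weeks alone, the subsets by scan day, the slide run as a block and the runs without an age were chosen after the data had been seen.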

Results

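Peripheral blood cells of female NOD mice, an inbred strain that develops autoimmune diabetes, were profiled at 6 ages on 37 microarrays. There were 8 arrays of 10-day-old mice, 3 of 4 weeks, 7 of 8 weeks, 8 of 12 weeks, 7 of 16 weeks and 4 of 20 weeks. Each array carried Cy3-labelled RNA of NOD blood cells beside Cy5-labelled RNA of NOD.B10 mice, which share the NOD background but carry the b haplotype of the H2 (MHC) region. A positive log2 ratio means a higher level in NOD. The series text names NOD.B10 groups of 10 days and of 20 weeks, with 10 mice each, and the sources used here do not say which of these RNAs went on which array. The labels do not say whether each array held the RNA of 1 mouse, so p-values measure the spread between these arrays, which may be partly technical. The 99th percentile of the spot signals lay between 195 and 4186 in Cy3 and between 2620 and 7700 in Cy5. Between 38.6% and 79.5% of spots were well above background in Cy3 and between 36.4% and 83.3% in Cy5. After filtering, 22184 genes were tested. The number of arrays limits the precision.

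Ages and scan days were nearly confounded. The arrays of 10 days, 12 weeks and 16 weeks, 23 in all, shared 1 scan day, and each of the other 3 ages had a day of its own. The NOD.B10 reference channel correlated across genes at 0.984 between 10-day arrays, 0.983 between 10 days and 12 weeks and 0.981 between 10 days and 16 weeks. It was 0.633 between 10 days and 4 weeks, 0.706 between 10 days and 8 weeks and 0.734 between 10 days and 20 weeks (genes are not independent replicates). Comparisons among 10 days, 12 weeks and 16 weeks therefore come first. All other age contrasts also compare scan days and cannot be told apart from them. Arrays of different ages could run against each other: the lowest correlation of 2 arrays over all probes was -0.562 (20 weeks replicate 1 with 8 weeks replicate 6), and 46 of 666 pairs lay below -0.3. The series text states the dyes, so the direction was kept.

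Transcripts of red blood cells were far lower, relative to the reference, at 12 weeks than at 10 days. Of the 38 measured genes of the erythroid list, 34 fell and 0 rose (also 34 and 0 adjusted over the list alone), with a median of -2.02 log2 units. Slc4a1, the anion exchanger of the red cell membrane, fell by 6.02 ± 0.41 (SE, 8 arrays per age). Car2, a carbonic anhydrase, fell by 5.99 ± 0.33, and Bnip3l, needed to clear mitochondria from maturing red cells, fell by 5.98 ± 0.44. The list's median was -3.06 with processed signals and -1.75 in the NOD channel alone, both also loess-normalized. Median centring, the only scaling without loess, gave -0.52. The list differed by limma's camera (adjusted p = 3.56e-24), and adjusted p = 0.332 with an estimated correlation. With the array as the unit, the list's median was 0.36 ± 0.45 (SD, n = 8) at 10 days and -1.57 ± 0.55 (SD, n = 8) at 12 weeks. The exact permutation test, two-sided, gave adjusted p = 0.00163 over 84 such tests (raw p = 0.000155, the smallest that 12870 splits can give).

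**Figure D1:**
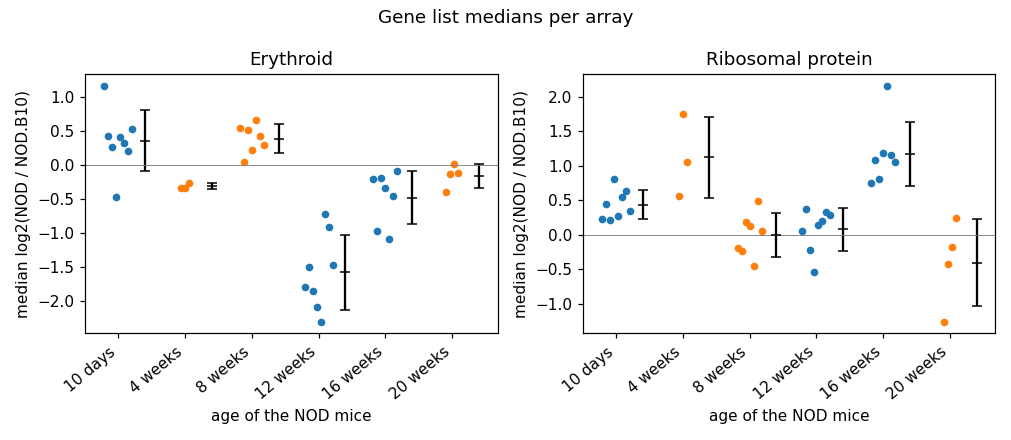
Median log2 NOD/NOD.B10 ratio of the erythroid list and of the ribosomal protein list on each array (y axis) against age group (x axis); points are arrays, blue for the scan day of 10 days, 12 weeks and 16 weeks and orange for other days, and bars are means with SD. The erythroid mean is 0.36 at 10 days, -1.57 at 12 weeks and -0.47 at 16 weeks, and the ribosomal mean is 0.08 at 12 weeks and 1.17 at 16 weeks, a rise that turns to a fall with median centring.

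The genes named by rule for this contrast changed by far more than 2-fold. Mkrn1, a ubiquitin ligase, fell by 7.31 ± 0.40 (158-fold). Map1lc3b, an autophagosome protein, fell by 7.01 ± 0.30 and the ferritin light chain pseudogene Ftl2-ps fell by 6.92 ± 0.35. H2-K1, a classical MHC class I heavy chain, rose by 4.00 ± 0.34 (16.0-fold). The list of MHC class I and peptide-loading genes did not follow, with 4 of 22 higher and 7 lower (4 and 8 adjusted over the list alone; median -0.18, but 0.67 with median centring; camera adjusted p = 0.347). Klf2, a transcription factor of resting T cells, rose by 4.78 ± 0.31. Its probes disagreed, and the mean of them gave 0.92, which did not pass the test. Limma's adjusted p ranged from 3.91e-18 for Map1lc3b to 1.34e-11 for H2-K1.

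Genes of cell division and respiration were lower at 12 weeks than at 10 days as well. In the proliferation list 20 of 33 genes fell and 2 rose (22 and 2 adjusted over the list alone; median -0.60, but -0.08 with median centring; camera adjusted p = 1.08e-06, and adjusted p = 0.674 with an estimated correlation). On this list 10 days replicate 4 stood apart, at 0.73 against -0.18 to 0.18, and the array medians differed by -0.43 with it and -0.34 without it (exact permutation p = 0.000311 and 0.000622). Ube2c, which tags mitotic proteins for degradation, fell by 4.26 ± 0.30. Nusap1, a spindle protein, fell by 3.48 ± 0.28, and Mki67, the Ki-67 antigen, fell by 2.35 ± 0.24. Among oxidative phosphorylation genes 26 of 47 fell and 9 rose (26 and 10 adjusted over the list alone; median -0.51, but 0.63 with median centring; adjusted p = 0.000112, and adjusted p = 0.702 with an estimated correlation). Ribosomal protein genes split, with 23 of 55 lower and 12 higher (27 and 13 adjusted over the list alone; median -0.62, but 1.42 with median centring, 0.18 with processed signals and 0.34 in the NOD channel alone; adjusted p = 0.00213, and adjusted p = 0.821 with an estimated correlation). Rpl28 fell by 5.12 ± 0.24 and Rps9 fell by 3.15 ± 0.24.

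Lymphoid and myeloid genes gave a mixed picture at 12 weeks, with the following values against 10 days. In the NK and cytotoxic list 11 of 21 genes rose and 1 fell (the same counts adjusted over the list alone; median 0.19, adjusted p = 0.0364, and adjusted p = 0.702 with an estimated correlation). The list was led by the chemokine Ccl5 at 1.75 ± 0.26 and the receptor Cd244a at 1.43 ± 0.23. In the interferon list 17 of 38 rose and 6 fell (19 and 6 adjusted over the list alone; median 0.23, adjusted p = 0.00521, and adjusted p = 0.702 with an estimated correlation). The GTPase Iigp1 rose by 2.27 ± 0.13, whereas the exonuclease Isg20 fell by 5.84 ± 0.34 and Isg15, a ubiquitin-like modifier, fell by 2.98 ± 0.33. Of candidate genes in diabetes susceptibility regions 11 of 21 rose and 2 fell (the same adjusted over the list alone; median 0.22, adjusted p = 0.0148, and adjusted p = 0.448 with an estimated correlation). Among them were the phosphatase gene Ptpn22 at 2.21 ± 0.21 and B2m, the light chain of MHC class I, at 1.75 ± 0.32. Immediate early genes had 11 of 31 higher and 3 lower (11 and 4 adjusted over the list alone; median 0.16, adjusted p = 0.0498, and adjusted p = 0.757 with an estimated correlation). The T cell list did not pass, with 4 of 24 genes higher and 5 lower. Il7r, the IL-7 receptor, rose by 3.06 ± 0.27, while Cd3g, a chain of the T cell receptor complex, fell by 1.89 ± 0.21. Neither did the neutrophil list (3 of 21 higher, 7 lower), the monocyte list (10 of 20 higher, 4 lower) nor the B cell list (5 of 18 higher, 3 lower). In the last, Cd24a, a surface protein also carried by red cell precursors, fell by 4.84 ± 0.39. The inflammatory cytokine Il1b rose by 3.01 ± 0.46. With the array as the unit the medians of the monocyte list did differ, by 0.41 (exact permutation test, adjusted p = 0.0372), and those of the inflammatory cytokine list by 0.10 (adjusted p = 0.0255, against 0.427 by camera). Of the 15 endocrine and 10 exocrine pancreas genes, included as transcripts not expected in blood, 0 were called by limma. The pancreas lists' adjusted p was 0.887 and 0.718, and for the endocrine list the median, at 0.0015, and the test differed in sign. Of 2 other lists of transcripts not expected in blood, muscle and skin genes had 4 of 16 lower and 0 higher (camera adjusted p = 0.187, permutation adjusted p = 0.176). Liver and plasma protein genes had 2 of 8 lower and 0 higher (median -0.12, but 0.01 in the NOD channel alone; camera adjusted p = 0.214). Per array the liver list's medians differed by -0.16 (permutation adjusted p = 0.00163, as for the erythroid list). In the platelet list 5 of 20 rose and 6 fell. Its median was -0.09, but 1.11 with median centring and 0.11 in the NOD channel alone, its mean 0.09, and its test pointed down (adjusted p = 0.718).

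In all, limma called 6981 genes in 12 weeks minus 10 days at adjusted p under 0.05, 4128 higher and 2853 lower, of which 1164 and 926 changed at least 2-fold. With median centring the split was 5490 higher and 897 lower. Within the 23 arrays of the shared scan day alone the count was 7308, and with the run of slide numbers as a further block it was 7648.

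By 16 weeks the erythroid deficit against 10 days was smaller, though not with median centring, where the list's median was -0.56 against -0.52 at 12 weeks. Of the 38 erythroid genes 21 were lower and 0 higher (24 and 0 adjusted over the list alone), with a median of -0.83 (camera adjusted p = 2.49e-24, and adjusted p = 0.332 with an estimated correlation). The median stayed negative under all scalings tried. Slc4a1 fell by 3.25 ± 0.43 (SE, 7 arrays against 8), Car2 fell by 3.07 ± 0.36 and Bpgm, which makes the haemoglobin ligand bisphosphoglycerate, fell by 2.55 ± 0.43. Proliferation genes were lower too, 18 of 33 with 0 higher (20 and 0 adjusted over the list alone; median -0.58, adjusted p = 6.65e-15, and adjusted p = 0.332 with an estimated correlation). Their array medians differed by -0.43, or by -0.34 without 10 days replicate 4 (exact permutation p = 0.000622 and 0.00117). Atf5, a stress-response transcription factor, fell by 3.47 ± 0.37 and Dntt, the terminal transferase of V(D)J joining, fell by 3.25 ± 0.46.

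Several groups were higher at 16 weeks than at 10 days, and their medians kept their sign under the scalings tried. Of 55 ribosomal protein genes 29 rose and 1 fell (30 and 1 adjusted over the list alone; median 0.73, adjusted p = 3.25e-19, and adjusted p = 0.448 with an estimated correlation). Leading members were Rps27 at 2.78 ± 0.33 and Rps7 at 2.76 ± 0.32. MHC class I and peptide-loading genes had 8 of 22 higher and 1 lower (9 and 2 adjusted over the list alone; median 0.22, adjusted p = 0.000191, and adjusted p = 0.702 with an estimated correlation). H2-K1 was at 2.80 ± 0.34 and B2m at 2.64 ± 0.33. Of megakaryocyte and platelet genes 5 of 20 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.64, adjusted p = 5.77e-05, and adjusted p = 0.702 with an estimated correlation; 0.0612, not passed, by the permutation test of array medians). The platelet chemokines Ppbp and Pf4 rose by 3.06 ± 0.58 and 2.12 ± 0.53. NK and cytotoxic genes had 7 of 21 higher and 0 lower (10 and 0 adjusted over the list alone; median 0.23, adjusted p = 5.77e-05, and adjusted p = 0.397 with an estimated correlation). Candidate susceptibility genes had 3 of 21 higher and 0 lower (6 and 0 adjusted over the list alone; median 0.18, adjusted p = 0.00163, and adjusted p = 0.352 with an estimated correlation). Smaller camera calls, each lost with an estimated correlation, came from 3 lists. Interferon genes were among them (7 of 38 higher, 3 lower, or 10 and 3 adjusted over the list alone; adjusted p = 0.0375, and adjusted p = 0.744 with an estimated correlation), as were immediate early genes (3 of 31 higher, 1 lower, or 4 and 1 adjusted over the list alone; adjusted p = 0.0242, and adjusted p = 0.744 with an estimated correlation). The last were glucocorticoid and glucose response genes (5 of 15 higher, 1 lower, or 6 and 1 adjusted over the list alone; adjusted p = 0.0413, and adjusted p = 0.543 with an estimated correlation).

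The genes named by rule as higher at 16 weeks were Srgn, the granule proteoglycan serglycin, at 3.38 ± 0.49 (10.4-fold), Shisa5 at 3.12 ± 0.39 and Nrgn, a calmodulin-binding protein, at 3.07 ± 0.50. Limma called 1807 genes, 1098 higher and 709 lower, of which 227 and 280 changed at least 2-fold. Scaling moved this contrast. There were 261 genes with median centring, 851 with scale normalization between arrays, where Shisa5, Nrgn and Slc4a1 no longer passed, and 3074 with the scanner's processed signals. The shared scan day alone gave 2028 genes, and 2288 with the slide run as a block.

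Between 12 and 16 weeks the erythroid genes moved back up. Of the 38, 30 rose and 0 fell (the same adjusted over the list alone), with a median of 0.98 that was 1.60 with processed signals, 0.80 in the NOD channel alone and only 0.08 with median centring (adjusted p = 6.65e-15, and adjusted p = 0.448 with an estimated correlation). Mkrn1 rose by 5.38 ± 0.42 (SE, 7 arrays against 8) and Ftl2-ps rose by 5.37 ± 0.36. The ferritin light chain Ftl1 rose by 4.92 ± 0.37 and Eraf, the alpha haemoglobin stabilizing protein, rose by 3.35 ± 0.36. The condensin subunit Smc4 fell by 2.37 ± 0.24 and Zadh2 fell by 2.35 ± 0.13.

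Ribosomal protein genes rose from 12 to 16 weeks in 45 of 55 cases and fell in 2 (the same adjusted over the list alone), a median of 1.42 that turned to -0.65 with median centring (adjusted p = 3.56e-24, and adjusted p = 0.360 with an estimated correlation). Per array this list's median was 0.08 ± 0.31 (SD, n = 8) at 12 weeks and 1.17 ± 0.46 (SD, n = 7) at 16 weeks. The exact permutation test, two-sided, gave adjusted p = 0.00163. Without 16 weeks replicate 5, which stood apart at 2.16, the difference was 0.93 in place of 1.09. Oxidative phosphorylation genes rose in 26 of 47 cases and fell in 5 (27 and 7 adjusted over the list alone), a median of 0.52 that turned to -0.58 with median centring (adjusted p = 1.21e-06, and adjusted p = 0.675 with an estimated correlation). Platelet genes rose in 9 of 20 cases and fell in 0 (10 and 0 adjusted over the list alone), a median of 0.74 that turned to -0.31 with median centring (adjusted p = 0.00111, and adjusted p = 0.757 with an estimated correlation). MHC class I genes rose in 12 of 22 cases and fell in 2 (13 and 2 adjusted over the list alone; median 0.30, but 0.01 with median centring; adjusted p = 0.00121, and adjusted p = 0.702 with an estimated correlation). H2-Q10 rose by 2.57 ± 0.22 while H2-M3 fell by 2.07 ± 0.18. Neutrophil genes rose in 8 of 21 cases and fell in 0 (9 and 0 adjusted over the list alone), a median of 0.26 that was -0.09 with median centring (adjusted p = 0.0242, and adjusted p = 0.799 with an estimated correlation; 0.0614, not passed, by permutation). Interferon genes fell in 15 of 38 cases and rose in 5 (the same adjusted over the list alone; median -0.12, adjusted p = 0.0375, and adjusted p = 0.744 with an estimated correlation). Limma called 5621 genes, 2479 higher and 3142 lower, of which 712 and 581 changed at least 2-fold. With median centring the split was 248 higher and 4955 lower. The shared scan day alone gave 5899 genes, or 6186 with the slide run as a block.

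Averaged over the 5 later ages, red cell genes were lower than at 10 days, which turned with median centring. At 8 weeks they were not lower, except in the NOD channel alone (median -1.42 against 10 days): the list's array mean was 0.39 there and 0.36 at 10 days, against -0.31 at 4 weeks, -1.57 at 12 weeks, -0.47 at 16 weeks and -0.16 at 20 weeks. Of the 38 erythroid genes 23 fell and 3 rose (25 and 3 adjusted over the list alone), a median of -0.83 that turned to 0.34 with median centring (adjusted p = 4.02e-11, and adjusted p = 0.656 with an estimated correlation). Map1lc3b fell by 3.52 ± 0.24 (11.5-fold), Bpgm fell by 3.49 ± 0.34, and Slc4a1 fell by 3.46 ± 0.34. Mkrn1 fell by 3.39 ± 0.33, and Eif5, a translation initiation factor, fell by 3.17 ± 0.24. Car2, Oaz1, Prdx2 (a peroxiredoxin abundant in red cells), Rnf10, Iscu, Ube2o and Ccndbp1 followed, with changes between -3.15 and -2.90. With median centring Oaz1, Prdx2, Rnf10, Iscu, Ube2o and Ccndbp1 kept their sign and no longer passed. The genes named as higher were Gramd1a at 1.43 ± 0.17 (2.70-fold), Tspan17 at 1.37 ± 0.23, Mif4gd at 1.33 ± 0.13 and Tle4, a transcriptional corepressor, at 1.28 ± 0.11. They were followed by Ap1b1, Arf3, Slc35c1, Prickle3, Nup153, Lasp1, Snx25 and Tspan14 between 1.09 and 0.92. Each of these 24 genes passed limma's test in the same direction at each of the 5 ages against 10 days.

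Among the lists, platelet genes had 10 of 20 higher and 0 lower than at 10 days (median 0.64, but -0.15 in the NOD channel alone; adjusted p = 0.00826, and adjusted p = 0.767 with an estimated correlation). Nrgn was at 2.21 ± 0.40. NK and cytotoxic genes had 11 of 21 higher and 1 lower (median 0.28, but -0.08 in the NOD channel alone; adjusted p = 0.00131, and adjusted p = 0.656 with an estimated correlation). Interferon genes had 21 of 38 higher and 4 lower (median 0.21, but -0.10 in the NOD channel alone; adjusted p = 0.00131, and adjusted p = 0.656 with an estimated correlation). Immediate early genes had 12 of 31 higher and 1 lower (median 0.24, but -0.23 in the NOD channel alone; adjusted p = 0.00260, and adjusted p = 0.656 with an estimated correlation). Candidate susceptibility genes had 10 of 21 higher and 1 lower (median 0.16, adjusted p = 0.00286, and adjusted p = 0.473 with an estimated correlation). Proliferation genes had 16 of 33 lower and 1 higher (median -0.35, but 0.19 with median centring; adjusted p = 4.53e-05, and adjusted p = 0.656 with an estimated correlation). Oxidative phosphorylation genes had 17 of 47 lower and 5 higher (median -0.13, but 0.90 with median centring; adjusted p = 0.00828, and adjusted p = 0.767 with an estimated correlation). Adjusted over the list alone, the higher and lower counts were 12 and 0, 12 and 1, 23 and 4, 12 and 1, 11 and 1, 1 and 16, and 9 and 18 for these 7 lists in the order given. The platelet list did not pass without the 4-week arrays (0.0891), with 12 and 16 weeks alone against 10 days (0.389) or with scale normalization (0.109). Oxidative phosphorylation did not pass without the 12-week arrays (0.122), with processed signals (0.3002) or with the value table (0.324). On probes above background on every array the interferon, NK, candidate and immediate early lists did not pass (0.461, 0.0846, 0.0752 and 0.0598). Limma called 7332 genes, 4339 higher and 2993 lower, of which 318 and 317 changed at least 2-fold, and 5703 genes where only 12 and 16 weeks stood against 10 days on the shared scan day.

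The other single ages against 10 days each compare scan days as well. At 4 weeks the GTPase Rnd3 was higher by 8.08 ± 0.36 and the GPI-anchored protein Ly6e by 6.25 ± 0.27. Nlrx1, a mitochondrial regulator of innate signalling, met the naming rule through a probe bright in Cy3 at 4 weeks alone. That probe's reference was well above background on 2 of the 3 arrays of 4 weeks, so no size is given here or below, and 2 other Nlrx1 probes had log2 ratios of -0.13 and 0.28. Bpgm fell by 3.88 ± 0.56, Slc4a1 fell by 3.78 ± 0.56 and Eif5 fell by 3.24 ± 0.39. Limma called 8866 genes, 5018 higher and 3848 lower. At 8 weeks the membrane protein Ms4a6b was higher by 2.56 ± 0.25, the imprinted gene Mest by 2.43 ± 0.45 and Mmd by 2.19 ± 0.37. Smap1 fell by 2.95 ± 0.34, Rnf10 fell by 2.91 ± 0.36 and E2f2, a cell cycle transcription factor, fell by 2.86 ± 0.43, although these 3 falls turned to rises of 0.33, 0.91 and 1.19 with median centring. Limma called 8904 genes, 4679 higher and 4225 lower. At 20 weeks the homeobox gene Hoxb6 was higher by 2.03 ± 0.26, Ankrd9 by 1.85 ± 0.24 and Gkn3 by 1.69 ± 0.25, with Ankrd9 at -0.09 in the NOD channel alone. Bpgm fell by 3.17 ± 0.51, the histone gene H3f3a fell by 2.95 ± 0.43 and Map1lc3b fell by 2.93 ± 0.37, and these 3 turned to 0.56, 0.72 and 0.52 with median centring. Limma called 5121 genes, 2619 higher and 2502 lower, or 3122 without 20 weeks replicate 1.

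From 4 to 20 weeks the steepest changes were falls, set by probes with very high NOD signals at 4 weeks. Rnd3 changed by -0.40 ± 0.02 log2 units per week, Ly6e by -0.33 ± 0.02 and the calcium-binding protein Pdcd6 by -0.31 ± 0.02. Togaram2, Polr3k, Atxn7, Bbs4, Ddx25, Senp2 and the platelet integrin Itga2b followed between -0.28 and -0.22. Nlrx1 and Rabl6, with references well above background on 2 of the 3 arrays of 4 weeks, fell as well, but Rabl6 was at 0.01 per week without these arrays. Pdcd6, Togaram2, Atxn7, Polr3k, Bbs4, Senp2, Nlrx1 and Rabl6 had probes bright at 4 weeks alone, so no level is read from these. Other probes did not show the high 4-week ratio: they were at -0.18 for Polr3k, 0.13 for Bbs4 and 0.56 for Senp2. Rises were small: Maip1 at 0.06 ± 0.01 per week, Pold4, a DNA polymerase subunit, at 0.05 ± 0.01, and Scnm1, Ror2, Eaf2, Slit1, Olfr738, Bmp1, Myo3b, Olfr1143, the clotting factor gene F9 and Ednrb between 0.05 and 0.04. Ednrb no longer passed the test without 4 weeks replicate 2 or with processed signals, no background correction or the NOD channel alone. Limma called 9762 genes, 4415 higher and 5347 lower with age. Over the 16 weeks 13 rose and 1669 fell at least 2-fold, a reading set after first counts.

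From 4 to 20 weeks 10 lists fell in the ratio, and the medians of 6 of them were above 0 in the NOD channel alone. Interferon genes fell in 28 of 38 cases and rose in 1 (median -0.04 per week, but 0.0015 in the NOD channel alone; adjusted p = 1.22e-05, and adjusted p = 0.473 with an estimated correlation). The GTPase Igtp was at -0.11 ± 0.02. Monocyte and macrophage genes fell in 15 of 20 cases and rose in 0 (adjusted p = 9.84e-05, and adjusted p = 0.656 with an estimated correlation). The protease gene Ctss was at -0.14 ± 0.03. MHC class I genes fell in 16 of 22 cases and rose in 1 (adjusted p = 0.000172, and adjusted p = 0.656 with an estimated correlation). H2-K1 was at -0.16 ± 0.03. NK and cytotoxic genes fell in 15 of 21 cases (adjusted p = 0.000520, and adjusted p = 0.656 with an estimated correlation), platelet genes in 13 of 20 (adjusted p = 0.00169, and adjusted p = 0.767 with an estimated correlation) and oxidative phosphorylation genes in 24 of 47 (adjusted p = 0.000379, and adjusted p = 0.722 with an estimated correlation). Ribosomal protein genes fell in 28 of 55 (adjusted p = 0.000520, and adjusted p = 0.767 with an estimated correlation) and T cell genes in 10 of 24 (adjusted p = 0.0137, and adjusted p = 0.767 with an estimated correlation). These 5 lists had 0 rises each and medians of 0.01 per week in the NOD channel alone for all 5. Immediate early genes fell in 17 of 31 cases (adjusted p = 0.000379, and adjusted p = 0.656 with an estimated correlation) and neutrophil genes in 9 of 21 (adjusted p = 0.0274, and adjusted p = 0.767 with an estimated correlation; 0.995 and a reversed direction without 4 weeks replicate 2), with 0 rises in both. Muscle and skin genes, not expected in blood, rose in 8 of 16 cases and fell in 1 (median 0.02 per week, but -0.0033 in the NOD channel alone; adjusted p = 0.00826, and adjusted p = 0.656 with an estimated correlation). Adjusted over the list alone the counts of falls were 28, 16, 16, 15, 14, 24, 28, 10, 18 and 9 for the 10 lists that fell, in the order given, and 8 muscle and skin genes rose. Without the 4-week arrays the ribosomal and neutrophil lists reversed (adjusted p = 0.758 and 0.0176) and the platelet list did not pass (0.0648). The T cell list did not pass without 4 weeks replicate 3 (0.0955), nor the neutrophil list without 20 weeks replicate 3 (0.0882). On probes above background on every array the ribosomal, oxidative phosphorylation, T cell and neutrophil lists reversed (0.603, 0.932, 0.975 and 0.650), and the interferon, monocyte, NK, platelet and immediate early lists did not pass (0.489, 0.243, 0.396, 0.650 and 0.224). Scale normalization ended the ribosomal and neutrophil calls (0.0723 and 0.0595).

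Between successive ages the largest steps went with the 4-week and 12-week arrays. From 4 to 8 weeks Nt5c3, a pyrimidine nucleotidase of red cells, rose by 2.54 ± 0.42, Eraf rose by 2.48 ± 0.47 and Trim10 rose by 2.40 ± 0.41. Fa2h, a fatty acid hydroxylase, fell by 9.27 ± 0.19 and Rnd3 fell by 7.90 ± 0.36, and Nlrx1 fell too. The Fa2h, Nlrx1 and Pdcd6 probes were bright in Cy3 at 4 weeks alone, so no transcript level is read from them. Limma called 5273 genes, 2240 higher and 3033 lower, or 3236 without 4 weeks replicate 2. From 8 to 12 weeks Klf2 rose by 4.13 ± 0.32, Rps7 rose by 3.37 ± 0.32 and Shisa5 rose by 3.36 ± 0.39. Ube2l6, an enzyme of ISG15 conjugation, fell by 6.16 ± 0.41, Ftl1 fell by 5.91 ± 0.37 and Dcaf12 fell by 5.89 ± 0.32. The mean of the Klf2 probes gave -0.12. Limma called 9429 genes, 4998 higher and 4431 lower. From 16 to 20 weeks Atf5 rose by 3.61 ± 0.45, Dntt rose by 2.68 ± 0.56 and Asns, the asparagine synthetase, rose by 2.46 ± 0.49. Rps7 fell by 3.71 ± 0.38, Rps23 fell by 3.28 ± 0.33 and Rps18 fell by 3.19 ± 0.38. The raw reference signal of Dntt was 2549 at 16 weeks and 658 at 20 weeks, so its rise also holds a fall of the reference. Atf5 stood apart on 20 weeks replicate 1, at 2.28 against -0.04 to 0.25 on the others. Limma called 5211 genes, 2306 higher and 2905 lower, or 2923 without 20 weeks replicate 1. With median centring Rps23 and Rps18 turned to 0.18 and 0.30 and Rps7 was at -0.28, none past the test. The moderated F test over the 5 later ages called 16105 genes. The genes named by their ranges of age means were Nlrx1, Rnd3 (8.14), Ly6e (7.06), Pdcd6 (6.21), Ube2l6 (6.16) and Ftl1 (5.91).

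Over all ages, the gene that differed most steadily between the strains was Ift140, an intraflagellar transport gene, at -1.18 ± 0.06 (2.27-fold lower in NOD, lower on 37 of 37 arrays; limma adjusted p = 4.13e-18). Zfp871 was at -0.48 ± 0.03, Unkl at -0.40 ± 0.04, the mast cell protease gene Prss34 at -0.28 ± 0.04 and the transcription factor gene Atf2 at -0.28 ± 0.04, followed by Mrps2, Rab7, Olfr668, Ccdc134 and Tollip between -0.27 and -0.18. Higher in NOD on at least 35 of 37 arrays were Mettl26 at 0.31 ± 0.04, Srm (spermidine synthase) at 0.23 ± 0.03, Pop7 at 0.22 ± 0.03 and Rnaseh2a, a subunit of ribonuclease H2, at 0.18 ± 0.02. Mettl26, Srm and Pop7 turned to -0.00, -0.26 and -0.30 with median centring. These were all the genes that met the naming rule. Without balanced dye swaps, a steady ratio holds any dye bias of its probe and leaves out the spread of the reference mice. The named NOD.B10 groups do not match every NOD age, so a ratio may also hold a difference of age. Strain variants under probes, which would also shift a ratio between the strains, were not tested.

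Ribosomal protein genes were higher in NOD over the ages in 38 of 55 cases and lower in 5 (39 and 5 adjusted over the list alone), a median of 0.41 that turned to -1.44 with median centring (adjusted p = 1.64e-12, and adjusted p = 0.656 with an estimated correlation). Erythroid genes were lower in 22 of 38 cases and higher in 3 (23 and 3 adjusted over the list alone; median -0.19, adjusted p = 0.000666, and adjusted p = 0.767 with an estimated correlation), but without the 12-week arrays the list's direction turned (adjusted p = 0.729). The proliferation and platelet lists below did not pass without them (0.492 and 0.285). NK and cytotoxic genes were lower in 11 of 21 cases (adjusted p = 0.00371, and adjusted p = 0.656 with an estimated correlation). Inflammatory cytokine genes were lower in 12 of 23 with 1 higher (adjusted p = 0.00223, and adjusted p = 0.473 with an estimated correlation), proliferation genes in 11 of 33 (adjusted p = 0.0126, and adjusted p = 0.767 with an estimated correlation) and platelet genes in 9 of 20 (adjusted p = 0.0188, and adjusted p = 0.779 with an estimated correlation; 0.0617 without 4 weeks replicate 1). Lower too were eosinophil, basophil and mast cell genes in 6 of 12 (adjusted p = 0.0274, and adjusted p = 0.473 with an estimated correlation; 7 adjusted over the list alone, the other lists unchanged). With median centring the eosinophil and inflammatory cytokine lists did not pass (0.440 for both). Without background correction the eosinophil, NK and platelet lists did not (0.106, 0.105 and 0.114), nor on probes above background on every array the NK and inflammatory cytokine lists (0.243 and 0.434). Limma called 10556 genes over the ages, 4868 higher and 5688 lower in NOD, but only 36 and 9 at least 2-fold, and median centring gave 3786 higher and 14850 lower.

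For the strain ratio at single ages the genes named by rule were as follows. These ratios may also hold differences of age. At 10 days Bpgm (2.96 ± 0.29), Rnf10 (2.84 ± 0.25) and Slc4a1 (2.75 ± 0.29) were highest, turning to -1.53, -1.42 and -1.70 with median centring, and Tsc22d1 (-2.09 ± 0.32), Mest (-2.02 ± 0.31) and Nptn (-2.01 ± 0.28) were lowest. Limma called 9812 genes, 4259 higher and 5553 lower. At 4 weeks Fa2h (9.13 ± 0.16), Rnd3 (7.48 ± 0.30) and Nlrx1 stood against Eraf (-1.85 ± 0.40), Nt5c3 (-1.34 ± 0.35) and Trak2 (-1.33 ± 0.27), with the Fa2h and Nlrx1 probes bright in Cy3 at 4 weeks alone. Limma called 6951 genes, 3777 higher and 3174 lower, or 3706 without replicate 2 of this age. At 8 weeks the cell cycle phosphatase gene Cdc25b (1.44 ± 0.29), Ftl1 (1.35 ± 0.27) and Trim10 (1.35 ± 0.23) were higher, and Retnlg, a resistin-like gene of neutrophils (-2.70 ± 0.37), Cstdc6 (-1.88 ± 0.39) and Wfdc21 (-1.58 ± 0.28) lower. Limma called 5799 genes, 2528 higher and 3271 lower, or 1206 with processed signals. At 12 weeks Klf2 (4.18 ± 0.22; the mean of its probes was 0.10 and did not pass) and Clic1 (8.57-fold) were higher, and Ube2l6 (-5.07 ± 0.28), Dcaf12 (-4.96 ± 0.22) and Mkrn1 (-4.76 ± 0.28) lower. Limma called 9504 genes, 4613 higher and 4891 lower, but 2663 and 7570 with median centring. At 16 weeks Pigt (3.68 ± 0.55), Lars2 (3.37 ± 0.51) and Rps7 (3.09 ± 0.23) were higher, turning to -1.32, -0.95 and -1.12 with median centring, and Atf5 (-2.94 ± 0.27), Dntt (-2.65 ± 0.34) and Asns (-1.96 ± 0.29) lower. Limma called 7252 genes, 3484 higher and 3768 lower. At 20 weeks Cntn1 (1.55 ± 0.15), Rasd2 (1.36 ± 0.14) and Celsr3 (1.34 ± 0.10) were higher, and Birc2, an inhibitor of apoptosis (-1.86 ± 0.37), the MHC class Ib gene H2-T23 (-1.85 ± 0.25) and Clic4 (-1.85 ± 0.34) lower. Limma called 4874 genes, 1761 higher and 3113 lower (1633, 805 higher and 828 lower, without replicate 1 of this age).

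Some genes at 4 weeks had reference spots not well above background on every array, which leaves only bounds. The NOD spot signal of Insc was at least 115-fold higher than the reference, that of Oosp1 at least 40.7-fold, Uros, an enzyme of haem synthesis, at least 34.8-fold, Pomgnt2 at least 16.6-fold and Gss at least 14.4-fold (limma adjusted p between 6.19e-31 and 5.39e-16). The brighter mean was set against the lowest signal well above background, and these bounds are open to dye bias. They bound spot signals, and no transcript level is read from them. Among 41 genes with another probe past the filter, the probes bright at 4 weeks alone had a median log2 ratio of 4.01 and the other probes of the same genes 0.07.

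The NOD.B10 reference channel itself differed between ages. The moderated F test called 18717 of 22184 genes. The genes named by rule were Nck2, Spock2, Gsx1, Gsdmcl1, Gpr37l1 and Slc22a12. Their reference spots were saturated on 2, 3, 2, 3, 1 and 2 of the 4 arrays of 20 weeks, in that order, so their ranges and rank are not given. Nck2, an adaptor protein gene, had a reference signal of 241 ± 84.4 (SD, n = 8) at 10 days, 268 ± 75.6 (n = 8) at 12 weeks and 262 ± 127 (n = 7) at 16 weeks. It was 17049 ± 1358 (n = 3) at 4 weeks, where 0 of its spots were saturated. Among the 3 ages of the shared scan day 390 genes passed limma's F test, and among 4, 8 and 20 weeks 6681 did. Age contrasts across scan days therefore divide by references that were not alike.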

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

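Weighed here are 3 patterns. The tests of other probes, of red cell numbers and maturation, and of the reference channel were chosen only after the results were seen, while the control oligonucleotide, dye normalization and the other splits of the arrays had their tests set first.

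At 4 weeks alone, 96 probes were at least 8-fold higher in NOD and under 2-fold at every other age, among them those of 9 named genes. The control oligonucleotide, a Cy3-labelled spike-in, might bind to these probes. On 8 weeks replicate 4, where its signal was 45218 against at most 5945 on the other arrays, these probes were shifted by -0.014. On 20 weeks replicate 3 (31907 against at most 9145) the shift was 0.022. These values argue against such binding at signals up to 45218. At 4 weeks the signal was 65178 on all 3 arrays, the value of saturated spots, so binding at higher levels stays open. Other probes of 41 of these genes, not bright by definition, had a median log2 ratio of 0.071 against 4.01. This argues against higher transcript levels in those only. Another labelled contaminant on the 4-week arrays may be the source, which was not tested, and all 3 arrays shared 1 scan day.

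Erythroid transcripts were lower at 12 weeks than at 10 days on arrays of 1 scan day. Dye normalization could account for part of it: the list's median was -0.518 in its weakest setting, median centring, against -2.02 here, and this value does not decide. Fewer red cells in the 12-week preparations as the whole cause stays open, because 26 of 124 markers of 6 other cell types were lower and 38 higher (21.0% lower), 19.4% with processed signals or the NOD channel alone, but 3.23% with median centring. Maturation of red cell output, alike at 12 and 16 weeks, stays open too, since the list's median in 16 weeks minus 12 weeks was 0.98 here and 0.081 in its smallest setting. A difference of age itself is likewise open.

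The NOD.B10 reference differed between scan days. Scanner and extraction settings alone are argued against by a mean correlation of 0.633 between the Cy5 signals of 10 days and 4 weeks, and another batch of reference RNA alone by a correlation of 0.781, across genes, between the shifts of Cy5 and Cy3 from day to day (genes are not independent replicates). Labelling or hybridisation that differed between the days is consistent with the same 0.781 and with 1046 genes over 4-fold brighter in both colours on the days of 4, 8 and 20 weeks and 0 dimmer. The age of the NOD.B10 mice behind each array was not tested. The Cy5 signal of Dntt was 2090 at 10 days, 2662 at 12 weeks and 2549 at 16 weeks. At 4, 8 and 20 weeks it was 268, 484 and 658. For Rag1 it was 663, 562 and 620 against 79.9, 86.1 and 296. Both were thus dimmer on the other days, unlike the 1046 genes, and these picked genes do not settle the age of the reference. Since 4, 8 and 20 weeks each have a day of their own, day and age cannot be told apart.

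Other splits into groups of the same sizes (100 each, the real one included, on 20342 genes without missing values) called fewer genes. The real count and the highest of the others were 6690 and 414 for the later ages minus 10 days, 8138 and 1536 for 4 weeks minus 10 days, 8209 and 2707 for 8 weeks minus 10 days, 6302 and 5101 for 12 weeks minus 10 days, 1581 and 508 for 16 weeks minus 10 days, and 4684 and 1060 for 20 weeks minus 10 days. They were 4839 and 2833 for 8 weeks minus 4 weeks, 8582 and 3846 for 12 weeks minus 8 weeks, 5043 and 3646 for 16 weeks minus 12 weeks, and 4653 and 1885 for 20 weeks minus 16 weeks. For any change from 4 to 20 weeks they were 14789 and 438, for the trend 8977 and 340, and for the reference channel 17169 and 12407. In these 13 results only the real split gave as many. This excludes neither shared RNA nor, across days, the scan day. The split of all arrays by scan day (4, 8 and 20 weeks against the rest) called 8439 genes. Of the real age contrasts only 12 weeks minus 8 weeks, the trend and any change had more. Within the shared day counts are from fits of 22184 genes, not set against the splits. They were 7308 for 12 weeks minus 10 days, 2028 for 16 weeks minus 10 days and 5899 for 16 weeks minus 12 weeks. For the numbers of lists called, chance is not excluded: the real number and the highest other were 8 and 13 for the later ages (17 splits gave as many), 11 and 14 for the trend (10 splits), 7 and 11 for 12 weeks minus 10 days (26 splits), 9 and 12 for 16 weeks minus 10 days (13 splits) and 7 and 11 for 16 weeks minus 12 weeks (27 splits).

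Arrays far from the others of their age were looked for by the gap to the nearest array over the whole range. Chance flags about 1 in 20 groups, 5 percent, and 51 of 721 groups tested stood out, or 14 of 165 among array measures and lists. Values are log2 ratios, unless called signals, against the range of the other arrays.

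On 10 days replicate 1, Ly6e was lowest at -0.86 against -0.36 to 0.06 (ratio 0.549). On 10 days replicate 2, Ms4a6b was highest at -0.22 against -1.87 to -1.15 (ratio 0.564). On 10 days replicate 4, the median of the T cell list was highest at 0.72 against -0.49 to 0.08 (ratio 0.530), the median of the proliferation list was highest at 0.73 against -0.18 to 0.18 (ratio 0.604), the median of the MHC class II list was lowest at -0.71 against -0.29 to 0.02 (ratio 0.572), Iscu was lowest at 0.70 against 1.97 to 3.09 (ratio 0.531), Mmd was lowest at -2.74 against -1.83 to -1.17 (ratio 0.582) and Retnlg was lowest at -2.16 against -1.23 to -0.72 (ratio 0.643). On 10 days replicate 6, the median of the granule precursor list was lowest at -0.08 against 0.04 to 0.14 (ratio 0.570) and Ednrb was highest at 1.40 against -0.33 to 0.44 (ratio 0.555). On 10 days replicate 8, Celsr3 was highest at 0.63 against 0.12 to 0.36 (ratio 0.532). On 8 weeks replicate 4, the Cy3 signal of the control oligonucleotide was highest at 45218 against 2118 to 5945 (ratio 0.911), Mest was lowest at -1.94 against 0.22 to 1.35 (ratio 0.657) and Nrgn was lowest at -2.68 against -0.65 to 0.43 (ratio 0.652). On 8 weeks replicate 6, the median of the oxidative phosphorylation list was highest at 0.57 against 0.03 to 0.26 (ratio 0.572) and Mettl26 was highest at 0.84 against 0.13 to 0.37 (ratio 0.652).

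On 12 weeks replicate 4, H2-T23 was lowest at -3.69 against -2.85 to -2.51 (ratio 0.708). On 12 weeks replicate 6, the median of the platelet list was highest at 0.08 against -1.27 to -0.85 (ratio 0.687), Eaf2 was highest at -0.02 against -0.49 to -0.27 (ratio 0.528), Prss34 was highest at -0.01 against -0.47 to -0.25 (ratio 0.532) and Tsc22d1 was highest at 0.46 against -2.48 to -1.38 (ratio 0.628). On 12 weeks replicate 7, Srm was lowest at -0.30 against 0.06 to 0.31 (ratio 0.591). On 16 weeks replicate 3, the median of the exocrine pancreas list was highest at 0.10 against -0.06 to -0.02 (ratio 0.695). On 16 weeks replicate 5, the median of the T cell list was highest at 0.42 against -0.20 to 0.01 (ratio 0.657), the median of the ribosomal protein list was highest at 2.16 against 0.76 to 1.18 (ratio 0.697), Bmp1 was highest at 0.73 against -0.23 to 0.16 (ratio 0.602), Klf2 was lowest at 1.20 against 1.93 to 2.48 (ratio 0.570), Rasd2 was highest at 0.60 against -0.08 to 0.12 (ratio 0.704), Ror2 was highest at 1.60 against 0.10 to 0.59 (ratio 0.675) and Slit1 was highest at 2.26 against 0.24 to 0.67 (ratio 0.787). On 16 weeks replicate 6, Ddx25 was lowest at -1.22 against -0.59 to -0.11 (ratio 0.569) and Tspan14 was highest at 0.45 against -0.29 to 0.01 (ratio 0.591). On 16 weeks replicate 7, Ftl1 was highest at 1.80 against -0.27 to 0.59 (ratio 0.582), Gsx1 was highest at 0.75 against -0.29 to 0.16 (ratio 0.573) and Mettl26 was lowest at -0.09 against 0.36 to 0.54 (ratio 0.711).

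On 20 weeks replicate 1, the median of the proliferation list was lowest at -0.21 against -0.09 to -0.07 (ratio 0.845), Atf5 was highest at 2.28 against -0.04 to 0.25 (ratio 0.875), Iscu was lowest at -0.40 against -0.05 to -0.02 (ratio 0.926), Itga2b was lowest at -1.27 against -0.37 to -0.21 (ratio 0.842), Ly6e was lowest at -0.69 against -0.09 to -0.05 (ratio 0.933) and Nlrx1 was lowest at -0.55 against -0.22 to -0.17 (ratio 0.852). On 20 weeks replicate 2, Scnm1 was highest at 0.92 against 0.72 to 0.73 (ratio 0.969). On 20 weeks replicate 3, the Cy3 signal of the control oligonucleotide was highest at 31907 against 4944 to 9145 (ratio 0.844), the median of the neutrophil list was lowest at -0.49 against -0.17 to -0.14 (ratio 0.912), Ankrd9 was highest at 0.70 against 0.03 to 0.10 (ratio 0.894), Hoxb6 was highest at 0.56 against 0.03 to 0.12 (ratio 0.831), Myo3b was highest at 0.70 against 0.32 to 0.33 (ratio 0.995), Ror2 was highest at 0.89 against 0.43 to 0.50 (ratio 0.848), Togaram2 was highest at 0.35 against -0.14 to -0.12 (ratio 0.970) and Ube2o was highest at 0.34 against -0.20 to -0.11 (ratio 0.845). On 20 weeks replicate 4, the median of the inflammatory cytokine and chemokine list was lowest at -0.18 against -0.08 to -0.07 (ratio 0.909).

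Differences between groups were found for 7 lists in 16 weeks minus 12 weeks by camera: erythroid (adjusted p = 6.65e-15), ribosomal protein (3.56e-24), oxidative phosphorylation (1.21e-06), platelet (0.00111), MHC class I (0.00121), neutrophil (0.0242) and interferon genes (0.0375). With an estimated correlation none of the 7 passed (adjusted p between 0.360 and 0.799), and with median centring the medians of the ribosomal (-0.65), oxidative phosphorylation (-0.58), platelet (-0.31) and neutrophil (-0.09) lists were reversed.

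Signals outside the main measurement came from control spots. The median Cy3 signal of the control oligonucleotide was 65178 at 4 weeks against 96.8 for the negative controls. At 8 weeks it was 3114 against 76.1 and at 20 weeks 8302 against 319. The 4-week value is that of saturated spots and so a lower bound. The median Cy5 signal of an E1A spike-in was 4970 at 10 days, 6587 at 12 weeks and 5305 at 16 weeks, where the median Cy5 signal of all probes was 94.7, 90.1 and 86.4. On the other scan days it lay between 95.7 and 109.7 on the 4-week arrays, 81.7 and 189 on those of 8 weeks and 301 and 318 on those of 20 weeks.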

How the results depend on the processing

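Median centring in place of loess reversed 17 of 152 values of named genes and 4 of 26 of lists, and left 7 and 2 short of the threshold. An estimated correlation left 26 of 26 lists short of it, and a 2-fold minimum 29 of 152 genes. Runs chosen after seeing the data are named under data processing. Of 3549 values of named genes under the alternatives 3444 kept direction and side of the threshold, 85 kept only the direction and 20 reversed; of 604 of lists 536, 56 and 12 did. Median centring moved the median of all genes by up to 0.196 log2 units, processed signals by up to 0.140 and the value table by up to 0.118. Aquantile after loess leaves the ratios as they are by construction. So do runs without single arrays of 4 or 20 weeks for contrasts that use neither age. The value table holds nearly the same ratios as the processed signals. The number of values that kept their direction was thus partly fixed in advance. Extraction version and scan day could not be fitted as random blocks because each age lies within 1 of them, nor slides, which held 1 array each. Signal over background limits dim genes: 30136 of 41174 probes passed the filter, and 3595 genes were well above background in both colours on every array, so that the counts under that filter are smaller by construction, as are those with a 2-fold minimum. For all other values the cause was not tested.

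Median centring gave 18636 (3786 higher) for the strain ratio over ages, 15715 (5194 higher) for the ratio at 10 days, 12416 (2460 higher) for the ratio at 4 weeks, 10444 (2057 higher) for the ratio at 8 weeks, 14626 (4204 higher) for the ratio at 16 weeks, 12199 (2149 higher) for the ratio at 20 weeks, 14959 (7888 higher) for the later ages minus 10 days, 16150 (7680 higher) for 4 weeks minus 10 days, 15605 (8832 higher) for 8 weeks minus 10 days, 261 (116 higher) for 16 weeks minus 10 days, 11178 (7010 higher) for 20 weeks minus 10 days, 9163 (7366 higher) for 8 weeks minus 4 weeks, 9632 (5995 higher) for 20 weeks minus 16 weeks, 15 for lists in the strain ratio over ages and 17 for lists in the later ages minus 10 days. It gave 2663 higher and 7570 lower for the ratio at 12 weeks (4613 and 4891 here), 5490 and 897 for 12 weeks minus 10 days (4128 and 2853) and 248 and 4955 for 16 weeks minus 12 weeks (2479 and 3142). Reversed were Mettl26 (-0.0031), Srm (-0.26) and Pop7 (-0.30) over ages, Bpgm (-1.53), Rnf10 (-1.42) and Slc4a1 (-1.70) at 10 days, Pigt (-1.32), Lars2 (-0.95) and Rps7 (-1.12) at 16 weeks, Smap1 (0.33), Rnf10 (0.91) and E2f2 (1.19) in 8 weeks minus 10 days, Bpgm (0.56), H3f3a (0.72) and Map1lc3b (0.52) in 20 weeks minus 10 days and Rps23 (0.18) and Rps18 (0.30) in 20 weeks minus 16 weeks. Lists reversed were erythroid (adjusted p = 0.0433), oxidative phosphorylation (2.5e-07) and proliferation (0.149) in the later ages minus 10 days and ribosomal protein (1.235e-05) over ages.

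Processed signals gave 1206 (729 higher) for the ratio at 8 weeks, 1795 (468 higher) for the ratio at 20 weeks and 3074 (1828 higher) for 16 weeks minus 10 days, and the values in the authors' table were 1407 (811 higher) for the ratio at 8 weeks, 1959 (564 higher) for the ratio at 20 weeks and 3042 (1828 higher) for 16 weeks minus 10 days. Scale normalization gave 4043 (2032 higher) for the ratio at 4 weeks, 851 (437 higher) for 16 weeks minus 10 days and 3032 (1324 higher) for 8 weeks minus 4 weeks. No background correction gave 790 (499 higher) for the ratio at 20 weeks, 2667 (1726 higher) for 20 weeks minus 10 days, 2755 (1649 higher) for 20 weeks minus 16 weeks and 4 for lists in the strain ratio over ages. An offset of 10 gave 2677 for the ratio at 8 weeks and 3048 for the ratio at 20 weeks, and array weights 3175 for the ratio at 8 weeks, 10392 for the ratio at 20 weeks, 8547 for 20 weeks minus 10 days and 9842 for 20 weeks minus 16 weeks. The NOD channel alone gave 12139 for the later ages minus 10 days, 13394 for 8 weeks minus 10 days, 14344 for 20 weeks minus 10 days and 2782 for the trend, with Ankrd9 reversed in 20 weeks minus 10 days (-0.091). The mean of a gene's probes reversed Klf2 in 12 weeks minus 8 weeks (-0.12). Only 4, 8 and 20 weeks gave 8354 for any change from 4 to 20 weeks.

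Probes well above background in both colours on every array gave 1865 for the strain ratio over ages, 1854 for the ratio at 10 days, 1690 for the ratio at 4 weeks, 948 for the ratio at 8 weeks, 2742 for the ratio at 12 weeks, 1247 for the ratio at 16 weeks, 1352 for the ratio at 20 weeks, 2053 for the later ages minus 10 days, 2045 for 4 weeks minus 10 days, 1509 for 8 weeks minus 10 days, 2711 for 12 weeks minus 10 days, 1266 for 20 weeks minus 10 days, 2143 for the trend, 1442 for 8 weeks minus 4 weeks, 2505 for 12 weeks minus 8 weeks, 2377 for 16 weeks minus 12 weeks, 1477 for 20 weeks minus 16 weeks, 3360 for any change from 4 to 20 weeks, 3503 for the reference channel, 5 for lists in the later ages minus 10 days and 2 for lists in the trend, with the neutrophil (adjusted p = 0.650), oxidative phosphorylation (0.932), ribosomal protein (0.603) and T cell (0.975) lists reversed in the trend. A 2-fold minimum gave 45 for the strain ratio over ages, 350 for the ratio at 10 days, 1044 for the ratio at 4 weeks, 66 for the ratio at 8 weeks, 1499 for the ratio at 12 weeks, 216 for the ratio at 16 weeks, 268 for the ratio at 20 weeks, 635 for the later ages minus 10 days, 1749 for 4 weeks minus 10 days, 545 for 8 weeks minus 10 days, 2090 for 12 weeks minus 10 days, 507 for 16 weeks minus 10 days, 435 for 20 weeks minus 10 days, 1682 for the trend, 1168 for 8 weeks minus 4 weeks, 1818 for 12 weeks minus 8 weeks, 1293 for 16 weeks minus 12 weeks, 623 for 20 weeks minus 16 weeks, 3982 for any change from 4 to 20 weeks and 7276 for the reference channel. An estimated correlation gave 0 lists over ages, 0 in the later ages and 0 in the trend, and fry gave 15, 18 and 19, a test that does not compare a list with other genes.

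Leaving out single arrays of 4 or 20 weeks gave 3706 (without 4 weeks replicate 2) to 7029 for the ratio at 4 weeks, 1633 (without 20 weeks replicate 1) to 5244 for the ratio at 20 weeks, 3122 (without 20 weeks replicate 1) to 5355 for 20 weeks minus 10 days, 3236 (without 4 weeks replicate 2) to 5400 for 8 weeks minus 4 weeks and 2923 (without 20 weeks replicate 1) to 5467 for 20 weeks minus 16 weeks. The neutrophil list's adjusted p in the trend ran from 0.000762 to 0.995, reversed without 4 weeks replicate 2, and was 0.0882 without 20 weeks replicate 3. The platelet list's over ages ran from 0.00472 to 0.0617 (without 4 weeks replicate 1), the T cell list's in the trend from 0.00284 to 0.0955 (without 4 weeks replicate 3), and the slope of Ednrb from 0.037 (without 4 weeks replicate 2) to 0.045. Without the arrays of 4 weeks Rabl6 (0.0077 per week), the neutrophil list (adjusted p = 0.0176) and the ribosomal protein list (0.758) reversed in the trend, and without those of 12 weeks the erythroid list over ages (0.729).

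Over all ages the replicate numbers of the titles did not pair the arrays. Of 74 pairs with 1 number 18 had deviations correlating over 0.1 (lowest -0.331, mean 0.020 against -0.00305 for different numbers). Between 4 and 20 weeks, 1 of the 15 pairs of ages, all 3 pairs did (lowest 0.116, mean 0.166 against -0.0589), and 5 of 37 arrays had their best partner under their own number. With the replicate number as a block the counts were 8786 for the strain ratio over ages, 7172 for the later ages minus 10 days, 6985 for 12 weeks minus 10 days, 1713 for 16 weeks minus 10 days, 5629 for 16 weeks minus 12 weeks and 9661 for the trend, and the block moved no count by over 1.5 times.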

Other observations

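The tests of genes near H2-K1 were chosen only after the results were seen. From 10 days to 12 weeks Hbb-y, a beta globin of the embryo, fell by 3.21 ± 0.29 (SE; reference spot saturated on 3 of 37 arrays), Hbb-bh1 fell by 1.22 ± 0.27 and Sox6, a repressor of embryonic globin, fell by 0.45 ± 0.12, while Bcl11a, a repressor of fetal globin, rose by 0.68 ± 0.11 (limma adjusted p between 4.35e-11 and 0.00234). From 12 to 16 weeks Hbb-y rose by 2.34 ± 0.30, Hbb-bh1 rose by 0.85 ± 0.28 and Bcl11a fell by 0.46 ± 0.12. In the NOD channel Hbb-bt, a beta globin of the adult, moved alike. It was at 17.3 log2 units at 10 days, 13.3 at 12 weeks and 16.8 at 16 weeks. Which transcripts the Hbb-y and Hbb-bh1 spots bound was not tested, so no level of embryonic globin is read from them. The list of 5 genes did not pass camera in either contrast (adjusted p = 0.193 and 0.292), with medians of -0.45 and 0.26.

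Antigen-presenting and antibody genes moved apart within their lists, none of which passed camera within the shared scan day. Ctss, the cathepsin that processes the invariant chain, rose by 2.78 ± 0.33 from 10 days to 12 weeks and fell by 1.63 ± 0.34 from 12 to 16 weeks, and Cd74, the invariant chain itself, fell by 0.93 ± 0.30 and then rose by 1.03 ± 0.31 (MHC class II list, adjusted p = 0.815 and 0.616). Zbtb46, a transcription factor of conventional dendritic cells, fell by 1.68 ± 0.24 and then rose by 0.96 ± 0.24 (dendritic cell list, adjusted p = 0.696 and 0.778). Ighm, the heavy chain of IgM, rose by 1.16 ± 0.38 and then fell by 1.45 ± 0.40 (plasma cell list, adjusted p = 0.887 and 0.866). Of 16 regulatory T cell and checkpoint genes 6 rose and 0 fell at 12 weeks against 10 days (adjusted p = 0.214 by camera, and 0.00962 by the permutation test of array medians, which differed by 0.13), with Il2rb at 0.60 ± 0.14 and Ikzf2 at 0.59 ± 0.11. Chil3, a chitinase-like protein of myeloid precursors, rose by 1.83 ± 0.35 and then fell by 1.54 ± 0.37 (granule precursor list, adjusted p = 0.930 and 0.611). The spot signal of Dntt in NOD was 805 ± 995 (SD, n = 8) at 10 days, 151 ± 29.9 (n = 8) at 12 weeks and 114 ± 14.9 (n = 7) at 16 weeks, and that of Rag1, a recombinase of lymphocyte precursors, was 307 ± 322, 105 ± 6.21 and 108 ± 15.7.

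Genes with a steady strain ratio may lie near the H2 region, in which the strains differ. Of 16666 genes placed in order on the chromosomes, 69 passed limma's test with 1 sign on at least 35 of 37 arrays. Within 50, 100, 200 and 400 genes on either side of H2-K1 there were 2, 2, 8 and 13 of them, 4.78, 2.40, 4.82 and 4.13 times the share over all placed genes (permutation p over random shifts of the gene order 0.0451, 0.164, 0.0098 and 0.0084). The window of 200 was run first. Among the 10232 genes well above background in both colours on a share of at least 0.5 of the arrays, 27 had such a ratio, and 2, 2, 6 and 8 of them lay in these windows (8.92, 4.59, 7.87 and 5.74 times the share; permutation p 0.024, 0.0637, 0.0108 and 0.0206). With a permutation p of 0.164 at 100 genes the H2 interval as the source and gene-specific dye bias alone (lowest enrichment 2.40) cannot be told apart. Strain variants under the probes were not tested and would shift such ratios too. The 8 genes above background were Ift140 (-1.18 ± 0.06), Zfp871 (-0.48), D17H6S56E-5 (-0.46), Unkl (-0.40), Prss34 (-0.28), Kat2b (-0.27), Trem1 (-0.19) and Mettl26 (0.31), the last of which was at -0.00 with median centring. The other 5 were not well above background in 1 colour on most arrays, so no ratio is given: Eif2ak2, Clcn7 and Ptcra (18, 17 and 15 of 37 arrays in Cy3) and Olfr94 and Fpr-rs4 (13 and 3 of 37 in Cy5). Genes outside the naming rule were picked after their values were seen.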
